A study of Homo sapiens with 6 samples.

How the data were processed

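Messenger RNA of iMicroglia, microglia-like cells made from human induced pluripotent stem cells, was sequenced from 3 GPNMB wild-type (WT) and 3 GPNMB knockout (KO) samples under the vehicle phosphate-buffered saline (PBS). Per the labels' protocols, both genotypes came from the iNGN line, a derivative of the PGP1 stem cell line that carries a doxycycline-inducible neurogenin transgene. Embryoid bodies gave floating myeloid progenitors, which were collected from day 20 on, every 8 days, and matured at 125000 cells per well in interleukin 34, M-CSF and TGFbeta until day 10 of maturation. The polyA libraries were made with a TruSeq kit and sequenced with single-end reads of 118 cycles. The kit's strand setting is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Genotype was taken from the genotype label of each sample, and the replicate number from its title. All 6 samples carry the same batch label. The labels call the samples biological replicates without saying whether they came from separate differentiations, so the p-values measure the spread between these samples. The labels name 1 cell line per genotype; the way the knockout was made and the number of clones are not given in the sources used here.

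The submitters' processing notes name kallisto 0.48.0 and the GRCh38 build; the transcript set and the fragment length setting are not given in the sources used here. Per the file headers, the deposited transcript tables hold kallisto's estimated counts and length-normalised abundances (TPM) for 205131 Ensembl transcripts in each library. The deposited gene table is called a count matrix, but its columns sum to between 976200 and 979271. For 76.4% of the gene symbols and libraries compared, its values equal the rounded sum of that library's TPM over the transcripts matched to the gene. It was therefore treated as a score, namely TPM that the authors summed per gene symbol and rounded to whole numbers. Such values carry no depth, and their rounding is coarse for low genes. Depth was read from the deposited estimated counts, which sum to between 7408901 and 12403267 per library.

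The main test, the gene lists, the rule for named genes and the first set of alternatives below were chosen before the data were examined. That design assumed gene counts and edgeR, and named limma-trend on log2(value + 1) as the test if the table held another unit. That second test was used for all main results. Genes listed at 2 or more in at least 3 libraries were kept, which left 13267. This filter was set after the values had been seen, when filters at 0, 1, 5 and 10 and a robust prior were also compared, and it has a large effect on the number of calls. Genotype was the only term, all 6 libraries entered the fit, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are KO over WT on the log2(value + 1) scale, which understates the change of low genes; plain folds are ratios of group means of the deposited values. Group values are means ± SD of 3 libraries, given as deposited values in TPM units. Transcripts of GPNMB were compared by an exact two-sided permutation test of the TPM, whose smallest possible p is 0.1 with 3 against 3. limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0 were run in R 4.3.3, with pandas 2.3.3 and matplotlib 3.10.9 in Python 3.11.15.

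The gene lists cover homeostatic microglia, disease-associated and lipid-associated microglia, phagocytic and scavenger receptors, lysosomal hydrolases and membrane proteins, the vacuolar ATPase, MiT/TFE factors and autophagy, cholesterol synthesis and uptake, lipid efflux and storage, MHC class II presentation, cytokines and NF-kB targets, interferon-stimulated genes, and immediate early genes. Others are p53 targets, proliferation, hypoxia and glycolysis, the unfolded protein and integrated stress response, mitochondrially encoded transcripts, extracellular matrix, melanosome and pigment genes, Parkinson disease genes, and markers of 11 other cell types or lineages. GPNMB is in none of them. Lists with 5 or more tested members (26 of 31) and the 22 autosomes were tested with camera at a preset correlation of 0.01 between genes, two-sided, with the correlation estimated per list and fry as alternatives. The genes named are GPNMB; up to 12 genes per direction with the largest fold change among those past the threshold, with a mean value of at least 5 in the higher group and no overlap between genotypes; and up to 4 members of each list, ranked by passing and then by p. This gives 119 genes, of which GPNMB and 48 others are named, picked after their values and their stability across settings had been seen; some others are not reported here. Chromosome Y genes and genes of X inactivation were neither tested nor named.

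For the alternatives that need counts, transcript identifiers were matched to GENCODE 29 without their version. Of the identifiers, 80.1% matched, and the matched transcripts hold between 88.1% and 88.7% of the estimated counts of a library. The estimated counts were rounded and summed per gene. Genes with newer transcripts are then summed only in part, so a further set held only genes whose summed TPM lay within 1 or 10% of the deposited value in all 6 libraries. Coordinates are those of GENCODE 29 on GRCh38, which need not be the annotation the authors used. GC content was taken from the longest GENCODE 29 transcript of each gene, known for 99.6% of the tested genes, and its trend was removed from each library by a loess fit with a span of 0.4.

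The first set of alternatives was size factors from DESeq2's method, no filter, a filter at 1, the replicate number as a block, leaving out each library, edgeR, DESeq2 and limma-voom on the summed estimated counts, and stricter thresholds. Those chosen after seeing the data were pseudocounts of 0.5 and 4, filters at 5 and 10, a robust prior, TMM scaling, removal of the GC trend, edgeR on completely matched genes, edgeR with the block, and edgeR on counts scaled from the deposited values. Samples with the same replicate number carried no label of a shared day.

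The tests were run on simulated data for the KO against WT comparison, with 200 genes changed at known folds. The changed genes were drawn only from genes above a minimum mean level, so the rates below do not cover the lowest genes tested. The adjusted threshold is also easier to pass with that many changed genes than in the data, where limma-trend called 16. The rates therefore do not give the power of the tests on the data. limma-trend, on 12931 genes, recovered 65% of the genes changed 2-fold and 99% of those changed 4-fold, with 13 false calls among 177. edgeR, on 13378 genes, recovered 76% and 96%, with 14 false calls among 186. Limma-voom on the same genes recovered 72% and 97%, and DESeq2 on 13641 genes 87% and 98%, with 39 false calls among 224. camera called the 1 shifted list and 0 of the others among 26 simulated lists. The genes of these lists were simulated independently, so the run does not show how camera at the preset correlation treats correlated members. In the data the estimated correlation reached 0.931, for mitochondrially encoded transcripts. No pair of libraries of a genotype differed by as little as sampling noise: the chi-square per degree of freedom between them was at least 4.8.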

Results

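The series profiled iMicroglia by bulk RNA-seq to ask how loss of GPNMB, a transmembrane glycoprotein of lysosomes and the cell surface, alters their transcriptome at baseline. iMicroglia are microglia-like cells derived from human induced pluripotent stem cells; here they came from an isogenic pair of WT and KO lines, with 3 libraries per genotype, all given PBS. The WT libraries 1 to 3 held 7408901, 9447590 and 8545773 estimated counts, and the KO libraries 1 to 3 held 8940002, 9622449 and 12403267. Gene levels below are deposited values on the TPM scale, rounded to whole numbers by the authors. KO library 3 stood apart from the others on the first principal component, at 50.5 against values between -26.8 and 2.2, and listed 14164 genes at 1 or more where the other libraries listed between 15136 and 15541.

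GPNMB (ENSG00000136235; GRCh38 chromosome 7, 23235967 to 23275108) fell in the KO libraries to 13.2% of its WT level. It was listed at 1282, 1393 and 1356 in the WT libraries, a mean of 1344 ± 56.5 (SD, n = 3), and at 178, 209 and 146 in the KO libraries, a mean of 178 ± 31.5 (SD, n = 3). Every library therefore followed its genotype label. The log2 fold change was -2.93 with a standard error of 0.14 and an adjusted p of 0.00134 (limma-trend). The fold change stayed between -3.05 and -2.79 without any 1 library, but the adjusted p rose above the threshold, to 0.0632 without WT library 2 and 0.0565 without WT library 3; over all alternatives it ranged from 3.31e-171 to 0.122.

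The loss was seen in all 4 protein-coding GPNMB transcripts. GPNMB-202, the most abundant, measured 686 ± 29.9 TPM in WT and 81.7 ± 12.5 TPM in KO (SD, n = 3 each; exact permutation p = 0.1, the smallest possible), or 11.9% of WT. GPNMB-201 stood at 8.6% of WT, GPNMB-215 at 11.3% and GPNMB-203 at 26.2%, each with an exact permutation p of 0.1. The shorter noncoding transcripts were mixed. GPNMB-208 stood at 35.5% of WT, lower in every KO library than in every WT library (exact permutation p = 0.1). GPNMB-211 stood at 37.8%, with overlapping libraries (exact permutation p = 0.2). GPNMB-209 and GPNMB-204 stood at 78.8% and 118.7% of WT, also with overlapping libraries (exact permutation p = 0.6 each). The coding transcripts made up 95.4% of GPNMB TPM in WT and 80.9% in KO. TPM divides by length, so these shares are not shares of reads. GPNMB-209 (513 nt) held between 15 and 23 estimated counts in a KO library, and GPNMB-202 (2763 nt) between 1108 and 1561. The tables do not give the position of the edit, and kallisto divides reads among transcripts that share exons, so the shares of single transcripts are estimates.

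**Figure D1:**
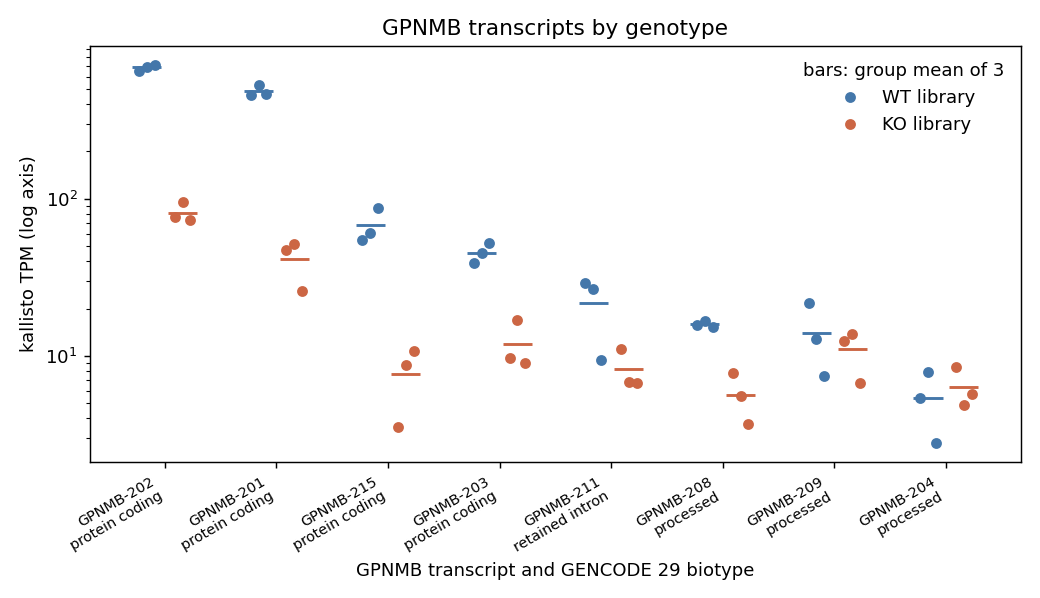
TPM of the 8 most abundant GPNMB transcripts (log axis) in each of the 3 WT and 3 KO libraries, with the mean of each group as a bar. The 4 coding transcripts and the noncoding GPNMB-208 lie lower in every KO library than in every WT library, while GPNMB-211, GPNMB-209 and GPNMB-204 overlap.

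Beyond GPNMB, few genes separated the genotypes. Of 13267 genes tested, 16 changed at an adjusted p under 0.05, 9 higher and 7 lower in KO. The genes that rose included the inflammatory mediators IL1B and CCL3, the class II antigen presentation chain HLA-DRA, the oxidised LDL receptor OLR1 and the collagen cross-linking enzyme LOX. Those that fell, besides GPNMB, included the mitochondrial thioredoxin reductase TXNRD2, the mitochondrial co-chaperone DNAJC15 and the AP-1 subunit FOSB.

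IL1B rose 3.79-fold, from 30.7 ± 4.16 to 116 ± 27.5 (log2 fold change 1.87, SE 0.19, adjusted p = 0.0338). CCL3, a chemokine with near-identical gene copies that can share its reads, rose 4.23-fold, from 44.7 ± 11.4 to 189 ± 40.7 (adjusted p = 0.0421). HLA-DRA rose from 256 ± 13.2 to 523 ± 66.3, OLR1 from 81.0 ± 5.29 to 164 ± 7.21, and LOX from 65.0 ± 2.65 to 132 ± 15.6, each about 2.02- to 2.04-fold. PKNOX1, a homeobox transcription factor, rose 5.54-fold, from 26.0 ± 8.54 to 144 ± 34.1. The ribosomal protein gene RPL9, which has many processed pseudogenes, rose 2.03-fold from 793 ± 59.2 to 1612 ± 133, a call that edgeR made on completely matched genes (log2 fold change 0.59, adjusted p = 0.0246) but not on all summed estimated counts (adjusted p = 0.0978), in a range from 0.00211 to 0.31 over the alternatives. The protocadherin PCDHGA10, whose last exons are shared with its gene cluster, was listed at 2 in each WT library and between 9 and 10 in KO. FOSB fell to 29.9% of WT, from 51.3 ± 10.5 to 15.3 ± 0.577 (adjusted p = 0.0338).

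A set of 6 of the changed genes was near 0 in 1 genotype, 5 of them in KO. TXNRD2 was listed at 30, 27 and 21 in WT and at 1, 2 and 0 in KO (adjusted p = 0.0338). DNAJC15 was listed at 17, 21 and 18 in WT and at 0 in every KO library (adjusted p = 0.00134), and its summed estimated counts were between 4 and 19 in KO against 237 to 327 in WT. TDO2, the liver-type tryptophan dioxygenase, was listed between 5 and 9 in WT and at 0 in KO, and the pseudogene PTCHD3P1 between 5 and 11 in WT and at 0 in KO.

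The number of calls was sensitive to the fit. edgeR's quasi-likelihood test on the summed estimated counts called 45 of 13649 genes, 28 higher and 17 lower, including 12 of the 14 limma calls that it tested, and all 14 moved the same way. Leaving out 1 library reduced the limma calls to 2, 0 and 0 without WT library 1, 2 or 3 and to 4, 2 and 3 without KO library 1, 2 or 3. Where the count was 0, 1150 and 1293 genes had an unadjusted p under 0.05. limma called 0 genes as higher in all 6 of these fits, with between 534 and 820 higher genes at an unadjusted p under 0.05. Over the same 6 fits the limma log2 fold change lay between 1.69 and 1.98 for IL1B, 1.85 and 2.26 for CCL3, 0.97 and 1.06 for OLR1, and 0.91 and 1.05 for LOX. edgeR called between 11 and 23 genes as higher and between 10 and 31 as lower in the same fits. GPNMB and DNAJC15 passed in 4 of the 6 limma fits. In the full fit 1484 genes had an unadjusted p under 0.05, and 14.7% of genes had no overlap between genotypes where chance gives 10%.

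**Figure D2:**
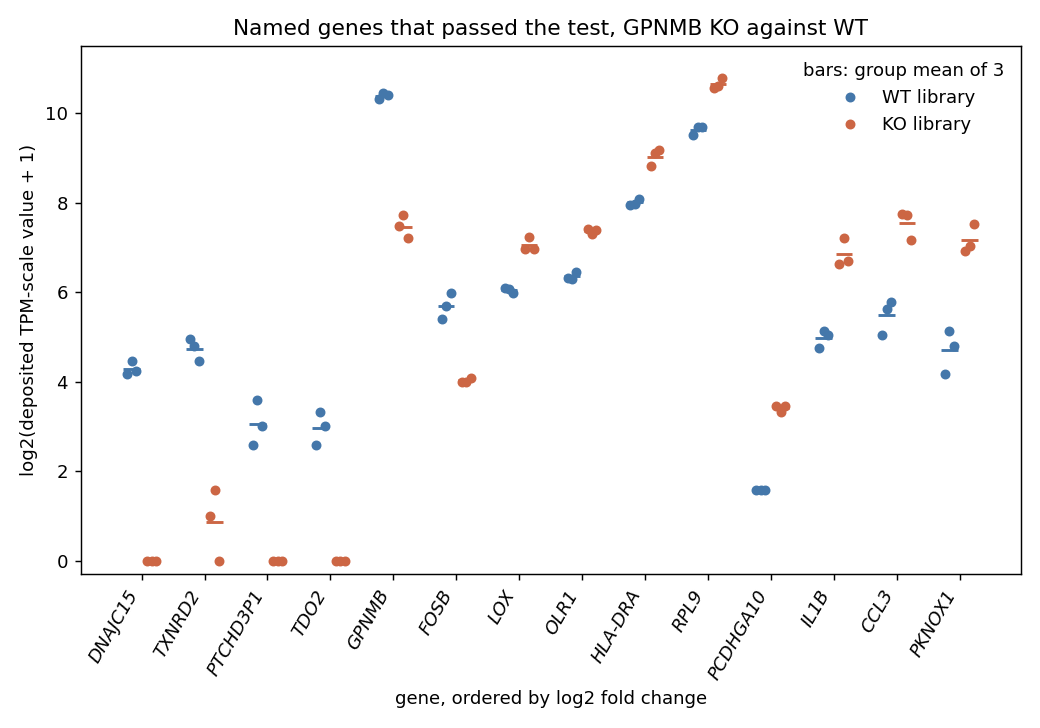
Deposited value of 14 of the 16 changed genes, as log2(value + 1), in each WT and KO library, with group means as bars, ordered by log2 fold change. DNAJC15, TXNRD2, PTCHD3P1 and TDO2 lie at 0 to 2 on the deposited scale in KO, and none of the 14 has overlapping genotypes.

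Inflammatory genes were higher in KO as a group in camera with the preset correlation. At that setting 4 of the 10 ways to split the libraries into 3 and 3, the genotype split among them, gave 4 or more lists. This limits each of the 4 lists that passed. Of 28 tested cytokines and NF-kB targets, IL1B and CCL3 rose, 26 did not pass over all genes, and 11 were higher when adjusted over the list alone. CCL4, a chemokine gene beside CCL3, was listed at 16.7 ± 6.11 in WT and 64.3 ± 14.0 in KO (adjusted p = 0.0984), and TNF at 16.3 ± 3.06 and 31.7 ± 0.577 (adjusted p = 0.168). The list's median log2 fold change was 0.36, with 20 members positive and 8 negative (camera adjusted p = 3.1e-06, preset correlation). With an estimated correlation the camera adjusted p was 0.322, in a range from 7.8e-08 to 0.322 over the 23 alternatives. In edgeR on the summed estimated counts with an estimated correlation, a fit outside these 23, it was 0.522.

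MHC class II genes were also higher. HLA-DRA rose, 14 of 15 members did not pass over all genes, and 5 were higher when adjusted over the list alone. HLA-DRB1 was listed at 93.7 ± 3.21 in WT and 156 ± 18.0 in KO, HLA-DPB1 at 33, 33 and 35 in WT and 52, 64 and 78 in KO, and HLA-DPA1 at 137 ± 31.0 in WT and 231 ± 8.51 in KO. The median log2 fold change was 0.36 (camera adjusted p = 4.58e-05, preset correlation; adjusted p = 0.215 with an estimated correlation), and fry, which tests whether members move one way on balance, gave an adjusted p of 0.0199. HLA genes are polymorphic paralogues whose reads a reference transcript set can miss or divide. HLA-DRA itself was not tested by edgeR, since its transcripts that matched GENCODE 29 held at most 3 estimated counts in a library. The list lost its call in edgeR on completely matched genes (camera adjusted p = 0.489, in a range from 1.12e-05 to 0.489 over the 23 alternatives). In edgeR on the summed estimated counts with an estimated correlation, a fit outside these 23, the camera adjusted p was 0.522.

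Genes of cholesterol synthesis and uptake were higher by a small amount. None of 24 members passed over all genes (9 at an unadjusted p under 0.05; 0 called by edgeR on the summed estimated counts and 1, SC5D, on completely matched genes), and 6 were higher when adjusted over the list alone. The sterol desaturase SC5D was listed at 84.7 ± 8.96 in WT and 146 ± 24.2 in KO, the methylsterol oxidase MSMO1 at 157 ± 6.35 and 261 ± 58.5, and the early pathway enzyme HMGCS1 at 103 ± 9.29 and 144 ± 14.0. The median log2 fold change was 0.30, with 19 members positive (camera adjusted p = 6.55e-05, preset correlation). With an estimated correlation the camera adjusted p was 0.322, in a range from 2.83e-06 to 0.322 over the 23 alternatives. In edgeR on the summed estimated counts with an estimated correlation, a fit outside these 23, it was 0.575.

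Mitochondrially encoded transcripts were lower. All 12 tested members had a negative fold change, with a median log2 fold change of -0.88, though none passed on its own in limma or in edgeR on the summed estimated counts or on completely matched genes (4 at an unadjusted p under 0.05; camera adjusted p = 3.22e-05, preset correlation; adjusted p = 0.833 with an estimated correlation, the members' correlation being 0.931, in a range from 2.81e-11 to 0.833 over the alternatives). Without KO library 3 the median was -0.47 (adjusted p = 0.00076). MT-ND4L, a complex I subunit, was listed at 1498 ± 486 in WT and 647 ± 356 in KO, MT-ND1 at 491 ± 124 and 253 ± 114, and the cytochrome oxidase subunit MT-CO3 at 3888 ± 801 and 2736 ± 523. The share of all values on mitochondrial genes was 3.13%, 2.57% and 1.8% in the WT libraries and 2.08%, 1.6% and 1.2% in the KO libraries, so the genotypes overlapped.

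Genes that define microglial states did not pass as groups, apart from 1 list in 1 alternative. Among the 21 tested lists with no member past the threshold in limma, 65 of 426 different members had an unadjusted p under 0.05 and edgeR on the summed estimated counts called 4, namely LPL, BTG2, F13A1 and STAB1. edgeR on completely matched genes called 12, those 4 and P2RY12, LYZ, SC5D and CD36, which were higher, and VCAN, LPCAT3, MMP9 and MKI67, which were lower. CD36 and MKI67 fall outside the naming rule and were chosen after their values were seen. None of 23 homeostatic microglia genes passed (camera adjusted p = 0.882): the purinergic receptor P2RY12 was listed at 10.3 ± 5.86 in WT and 21.0 ± 4.00 in KO, complement C1QB at 3781 ± 463 and 2899 ± 204, and TGFBR1 at 257 ± 2.65 and 331 ± 5.29. None of 27 genes of disease-associated and lipid-associated microglia passed (adjusted p = 0.247), and the list passed as higher in 1 of 23 alternatives, with the GC trend removed (median log2 fold change 0.13, adjusted p = 0.0238, in a range from 0.0238 to 0.943). In the main fit 18 members of that list were positive and 9 negative, and the members summed to a mean of 32390 in WT and 30030 in KO. Its lipase LPL was listed at 17.0 ± 1.73 in WT and 31.7 ± 6.66 in KO. Among 32 phagocytic and scavenger receptors OLR1 rose and 31 did not pass (adjusted p = 0.511), and when adjusted over the list alone 3 were higher and 1 lower. The scavenger receptor MSR1 was listed at 220 ± 44.6 and 430 ± 14.2 (adjusted p = 0.097), and STAB1 at 1545 ± 189 and 964 ± 179. edgeR on the summed estimated counts called LPL and MSR1 higher and STAB1 lower.

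GPNMB is a target of the MiT/TFE factors that drive lysosomal genes, and the lysosomal lists did not pass. None of 49 lysosomal hydrolases and membrane proteins passed (adjusted p = 0.891), with the acid lipase LIPA at 339 ± 23.6 in WT and 452 ± 48.6 in KO and the cathepsin CTSK at 26.7 ± 2.31 and 41.0 ± 9.17. None of 19 vacuolar ATPase genes passed (adjusted p = 0.511), and none of 24 MiT/TFE factors and autophagy genes (adjusted p = 0.753). Among 28 genes of lipid efflux and storage none passed over all genes (adjusted p = 0.511), 2 were higher when adjusted over the list alone, and the oxysterol receptor NR1H3 was listed at 34.0 ± 2.00 and 51.7 ± 2.08. None of 29 Parkinson disease genes passed (adjusted p = 0.882), with RAB32 at 126, 151 and 169 in WT and 196, 184 and 220 in KO. None of 9 melanosome and pigment genes passed (adjusted p = 0.753).

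Signalling, stress and growth lists were mixed. Among 22 immediate early genes FOSB fell and 21 did not pass (adjusted p = 0.891), and when adjusted over the list alone 2 were higher and 2 lower; its relative FOS was listed at 778 ± 135 in WT and 459 ± 20.0 in KO, and BTG2 at 155, 174 and 174 in WT and 233, 301 and 233 in KO. None of 36 interferon-stimulated genes passed (camera adjusted p = 0.882), but the list followed single libraries. Its median log2 fold change was -0.25 without KO library 3 (adjusted p = 0.000864) and 0.30 without KO library 2 (adjusted p = 0.000229). The camera adjusted p ranged from 0.000229 to 0.985 over the 23 alternatives. The antiviral membrane protein IFITM3 was listed at 1040, 681 and 1749 in the KO libraries. None of 30 proliferation genes passed (adjusted p = 0.122). The list passed as lower in 5 of 23 alternatives, among them edgeR on the summed estimated counts (adjusted p = 0.00446, in a range from 0.00446 to 0.833 over the alternatives; adjusted p = 0.522 in that edgeR fit with an estimated correlation). The replication licensing factor MCM2 was listed at 35.7 ± 1.53 and 23.3 ± 3.06. None of the members passed among 24 p53 targets (adjusted p = 0.401), 26 unfolded protein and integrated stress response genes (adjusted p = 0.401) and 30 hypoxia and glycolysis genes (adjusted p = 0.487). The hypoxia and glycolysis list passed as lower without KO library 3 (median log2 fold change -0.06, camera adjusted p = 0.0217, in a range from 0.0217 to 0.895 over the 23 alternatives). Among 15 extracellular matrix genes LOX rose and 14 did not pass (adjusted p = 0.882), when adjusted over the list alone 1 was higher and 3 lower, and the protease inhibitor TIMP1 was listed at 593 ± 101 and 372 ± 64.1.

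Markers of other cell types did not pass as lists. The adjusted p was 0.48 for 13 markers of border macrophages, 0.882 for 14 of monocytes, 0.92 for 10 of osteoclasts and multinucleated cells, 0.753 for 5 of endothelial cells and 0.882 for 6 of pluripotent cells. When adjusted over the list alone, 3 border macrophage markers were lower; F13A1 was listed at 463 ± 49.4 in WT and 302 ± 36.0 in KO and LILRB5 at 151 ± 6.66 and 108 ± 13.2. Among the monocyte markers, of which 1 was higher and 1 lower when adjusted over the list alone, LYZ was listed at 253 ± 19.2 and 398 ± 28.1 and VCAN at 91.0 ± 4.00 and 60.3 ± 12.1. Markers of erythroid and megakaryocyte cells summed to 223, 125 and 49 in the WT libraries and to 193, 2081 and 845 in the KO libraries (adjusted p = 0.466 over 8 members). Most of that was the alpha globin HBA2, whose reads are shared with a near-identical copy, at 150, 1725 and 726 in KO, and the fetal globins HBG1 and HBG2, whose near-identical sequences also share reads, were listed at 1, 109 and 22 and at 4, 26 and 20 in KO. Lists with fewer than 5 tested members were not tested with camera. Their members summed to between 7 and 16 in a library for neurons, 6 and 14 for haematopoietic progenitors, 59 and 78 for mast cells, basophils and eosinophils, 5 and 21 for stromal and mesenchymal cells, and 28 and 74 for epithelial and hepatic endoderm cells. Signs differed within some lists that did not pass: the median was negative and the camera direction up for monocyte markers, lysosomal genes and phagocytic receptors, and the median was positive and the mean negative for extracellular matrix genes and for osteoclast markers, whose camera direction was down.

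**Figure D3:**
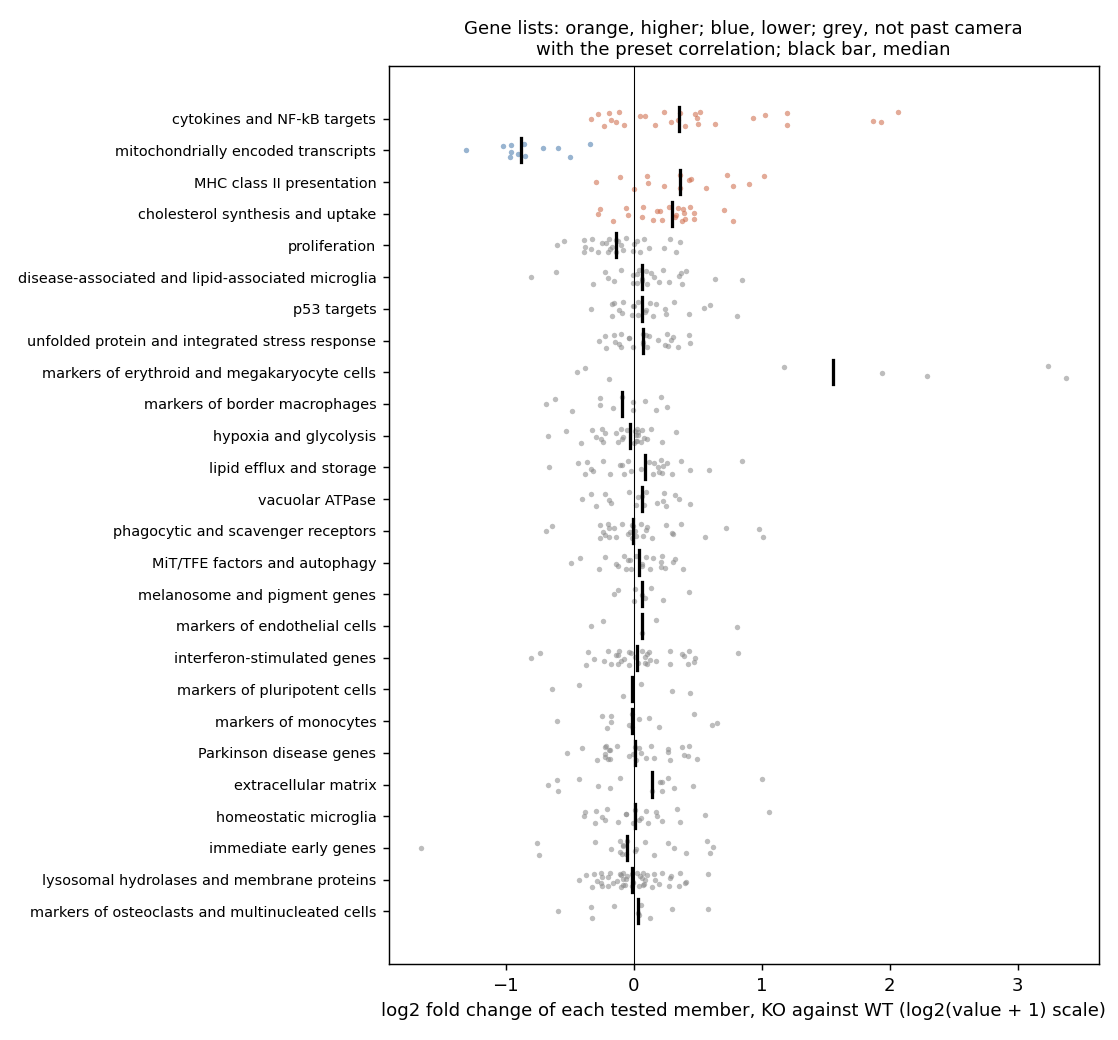
Log2 fold change, KO against WT, of each tested member of the 26 tested lists, with the list's median as a black bar. Cytokines and NF-kB targets, MHC class II and cholesterol genes lie mostly above 0 and mitochondrially encoded transcripts below it; the grey lists did not pass camera.

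Because the labels name 1 line per genotype, the autosomes were compared for shifts that a gain or loss of a chromosome would give. With the preset correlation 5 of 22 autosomes passed camera, with small medians: chromosomes 19, 16 and 22 were lower, with median log2 fold changes of -0.14, -0.12 and -0.11, and chromosomes 13 and 4 were higher, at 0.09 and 0.04. A whole extra or missing copy was not seen in any of these medians. Across the 22 autosomes, the median fold change followed the median GC content of the transcripts (Pearson r = -0.96 and Spearman rho = -0.93, each with a permutation p of 1e-05, the smallest that 1e+05 permutations can give; r = -0.94 without the 2 farthest autosomes; 1 relation was computed). Chromosomes are not independent replicates in this relation. The GC slope of log2 values was 0.98, 0.43 and 0.34 per unit of GC fraction in the WT libraries and -0.41, -1.05 and -0.29 in the KO libraries, relative to the mean of all 6.

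With the GC trend removed, camera passed 0 of 22 autosomes, 0 of them at an unadjusted p under 0.05, and with an estimated correlation it also passed 0, with 0 at an unadjusted p under 0.05 and an adjusted p of 0.958 for each of the 5. Without KO library 2 it passed 0, with 6 at an unadjusted p under 0.05; without WT library 1 it passed 1 and without KO library 1 it passed 2.

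**Figure D4:**
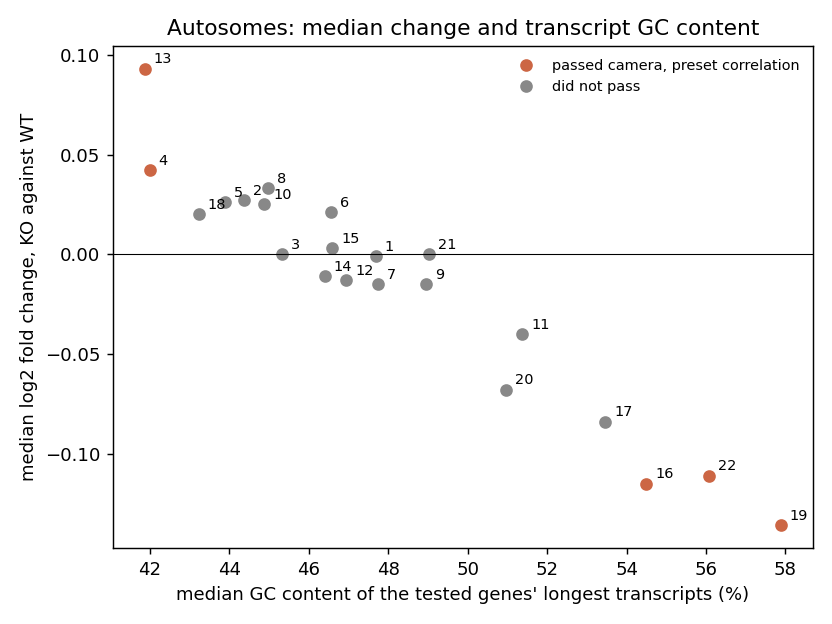
Median log2 fold change of the tested genes of each autosome, KO against WT, against the median GC content (%) of their longest transcripts; each point is 1 autosome, and the 5 in orange passed camera with the preset correlation. Chromosome 19, the most GC-rich, lies lowest at -0.136 and chromosome 13 highest at 0.093.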

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

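Alternatives named in the methods as chosen after seeing the data were tested only then; the rest were planned. The 16 changed genes became 29 with DESeq2's size factors, 29 with TMM, 27 with a robust prior, 25 with the GC trend removed, 7 with a filter at 1 and 3 with none; filters at 5 and 10 gave 24 and 23. Of the 16 genes, 16 were kept with size factors, TMM and the robust prior, 15 with the GC trend removed, 7 and 3 with a filter at 1 and none. At an adjusted p under 0.01, 3 genes were left. On summed estimated counts, edgeR called 45 genes, limma-voom 41 and DESeq2 233, and edgeR on completely matched genes called 116. Leaving out 1 library gave 0 to 4 genes with limma, where fewer libraries were fitted. Replicate numbers share only a number: the correlations of same-numbered libraries were 0.13, -0.013 and 0.053, and not every library correlated best with its own number. With the replicate block limma called 0 genes, with 1420 at an unadjusted p under 0.05, and edgeR called 74; GPNMB stood at -2.926 with an adjusted p of 0.122, in a fit with fewer residual degrees of freedom. The block gave 4 lists and 4 autosomes. The GPNMB log2 fold change ranged from -3.05 to -2.793 without 1 library. The transcript GPNMB-202 kept between 10.9% and 12.6% of WT. The 4 changed lists were 4 to 6 without 1 library, 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 1 with fry. The interferon list reversed to -0.254 without KO library 3 and passed at 0.298 without KO library 2. The 5 shifted autosomes were 8 in edgeR and limma-voom on summed estimated counts and 8 in edgeR on completely matched genes, 1 with no filter and 1 with a filter at 1, 0 with the GC trend removed, 0 with an estimated correlation, and 0 to 5 without 1 library. Except for the GC trend and for fits with fewer libraries or genes, the cause was not tested. The naming rule gave 118 genes besides GPNMB: 68 of their 2612 values in 23 other settings lay in the opposite direction, in 19 genes, 0 of them among the changed ones. The 48 of these that are named were picked after these values were seen, so that their 1067 values in the same direction are a selected count; of the values for the 13 named changed ones, 159 of 204 passed where all libraries were kept and 4 of 78 where 1 was left out. Depth limits low genes: a value of 1 is the rounding step of the deposited table.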

Other observations

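The tests of read assignment, cell lines, handling and wild-type cells were chosen only after the results were seen. edgeR on the summed estimated counts added genes that the deposited values did not call. Genes outside the naming rule are named here after their values were seen. Among them CD83, an activation marker of antigen-presenting cells, rose (edgeR log2 fold change 1.10, adjusted p = 0.0115), as did IL1A, a relative of IL1B (1.29, adjusted p = 0.0408), and PTPN6, a phosphatase that restrains myeloid signalling, fell (-0.94, adjusted p = 0.00108). NEUROG1, a proneural factor, was at 5, 3 and 2 estimated counts in WT and 90, 53 and 73 in KO. The lines carry a neurogenin transgene, and whether these reads come from the transgene or the gene itself was not tested. The zinc finger gene ZNF680 was at 5, 2 and 2 and at 71, 106 and 111. ZNF251 was at 54, 42 and 59 and at 2, 0 and 0 estimated counts, while its deposited values, 8, 6 and 11 against 25, 12 and 7, overlapped. The deposited MYH10 value, 2923, 2713 and 2651 in WT and 4411, 1567 and 2632 in KO, came almost wholly from a transcript absent from GENCODE 29, since the MYH10 transcripts that matched held between 0.08 and 2.09 TPM.

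The 6 genes near 0 in 1 genotype do not look like the loss or gain of a long chromosome segment. Their 25 tested neighbours within 500 kb had a median log2 fold change of 0.144 in the direction of the gene, and 0 of the 25 passed. The 95% bootstrap interval was -0.001 to 0.236, from resampling the neighbours and not the libraries. A loss limited to the genes themselves stays open. Summing the estimated counts per gene left 4 of the 6 genes past edgeR's threshold in the same direction, TXNRD2 and DNAJC15 among them. This argues against the authors' gene assignment as the source for these 4. TDO2 did not pass edgeR (log2 fold change -2.51, adjusted p = 0.109), at 9, 23 and 17 estimated counts in WT and 2, 2 and 6 in KO. PTCHD3P1 was not tested and held 8, 19 and 12 in WT and 0 in each KO library. Both were lower in KO, but with counts this low gene assignment stays open for them. With 1 cell line per genotype named in the labels, and the number of clones not given in the sources used here, a difference between the lines that is unrelated to GPNMB and an effect of GPNMB loss cannot be told apart.

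The higher cytokine and NF-kB target genes were weighed against 3 technical explanations. The monocyte markers had a median log2 fold change of -0.013 (95% bootstrap interval -0.177 to 0.195), so they did not rise as a list. The interval's upper end lay below the 0.355 of the cytokine list, but that list's own interval, 0.069 to 0.511, overlaps it. These intervals resample the genes of a list, not the libraries, so more monocyte-like cells stay open. LYZ, an abundant monocyte gene, was at 0.65. The immediate early genes, which handling would raise, had a median of -0.054 (interval -0.104 to 0.162), so the list as a whole did not rise. This interval also lay below 0.355 and overlapped that of the cytokine list. Members of the immediate early list went both ways, with BTG2 at 0.60, FOS at -0.74 and FOSB at -1.66. Handling that raises part of them therefore stays open. No library decided the direction: without 1 library the list's median log2 fold change lay between 0.286 and 0.425. The highest unadjusted camera p in these fits was 3.72e-05, at the preset correlation, which takes the members as nearly independent. With an estimated correlation the unadjusted camera p was 0.036 with all libraries, and leaving out libraries was not run with it. How far the strength of the shift rests on 1 library is therefore not settled. An effect of GPNMB loss on inflammatory genes may be followed up as a hypothesis, but the line difference also stays open, and with an estimated correlation the list had an adjusted p of 0.322.

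GPNMB transcript remained in the KO libraries at 10.9% to 15.6% of the WT mean. Reads of the paralogue PMEL do not account for it, since PMEL was listed at no more than 2 in a KO library. Cells of the WT line in the KO cultures would bring every WT transcript at a like share, but the means of the genes near 0 in KO reached at most 3.85% of WT (TXNRD2). In single KO libraries TXNRD2 reached at most 7.69%, in KO library 2, where GPNMB stood at 15.6%. These genes were picked as near 0 in KO, and unedited cells of the KO line could lack them too. Such cells therefore stay open. A transcript that is made but reduced in the edited line is a possible explanation that was not tested further.

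Of the 10 ways to split the 6 libraries into 3 and 3, the genotype split gave 16 genes and the highest of the others 1; 1 split gave as many. For lists, the genotype split gave 4 and the highest of the others 5, and 4 of the 10 splits gave 4 or more. For autosomes, the genotype split gave 5 and the highest of the others 0, with 1 split as large. With 10 splits no share can fall under 0.05.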
